A study of Homo sapiens with 6 samples.

How the data were processed

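RNA of MCF-7 cells was hybridised to Affymetrix whole-transcriptome 3' expression arrays, with 3 control samples and 3 samples given 100 µM ATP for 24 h. Total RNA was extracted with Trizol and biotin-labelled, per the labels' protocols. The deposited values are intensity values on a linear scale, 1 per probe set, and were made with RMA, per the submitters' processing notes. RMA subtracts background, sets all arrays to the same distribution of signals by quantile normalisation and summarises the probes of a probe set. The version of RMA and the settings are not given in the sources used here. That the table is linear was read from its values, which on control replicate 1 run from 3.84 to 16008, and log2 was taken before any test. Quantile normalisation gives every array nearly the same distribution, so a change of most transcripts in 1 direction is not visible in these values and each change is relative to the other genes. The median log2 signal lay between 4.94 and 5.00 on the 6 arrays. Scanner images and probe-level files were not used here, and all 6 columns of the table were used.

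Probe sets were named from the platform annotation. Of 54675 probe sets, 41097 had 1 gene symbol, 1801 had several and 11777 had no listed gene. Of 62 control probe sets, 56 had no listed gene and 6 had 1 symbol. Symbols were checked through the gene number against a RefSeq gene table (assembly GRCh38.p14), which matched 41043 of the probe sets with 1 symbol, and 54 kept the symbol of the array. No genome coordinates are reported. Probe sets with several symbols named no gene. For each of 19775 genes the probe set with the highest mean over the 6 arrays was taken, and 10523 genes had more than 1 probe set. Control probe sets were left out of the tests and no filter on level was applied.

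The groups were compared with limma 3.58.1 in R 4.3.3, by lmFit and eBayes on the log2 values of all 6 arrays, two-sided, without covariates. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. The number of arrays limits the precision. For 23 gene lists fixed from textbook knowledge, camera with an inter-gene correlation preset at 0.01 compared the members with all other genes, adjusted over the lists, and camera with a correlation estimated from the residuals and fry were run beside it. Of the 12 lists past the threshold with the preset correlation, 9 upward and 3 downward, 0 passed with the estimated correlation, where the lowest adjusted p was 0.14, and 8 of the 23 lists passed by the directional test of fry, which does not compare a list with other genes. Members of each list were also adjusted over the list alone. The lists covered receptors and enzymes of extracellular nucleotides, signalling, stress, metabolic and proliferation programmes and markers of fibroblasts, leukocytes and basal breast lines, and some genes stand on more than 1 list.

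The genes named were the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, up to 4 members of each list with the smallest p, and a set of 21 genes named whatever their values because they are known from work on ATP, invasion, drug resistance and hormone response in breast cancer. Some of that work may rest on these arrays, so the direction of such genes is not independent evidence. Genes with only a locus or open reading frame name were counted but not named. Of 124 named genes 81 were called. The design, the lists and this rule were set before the data were examined.

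The test was tried on simulated data for the same 19775 genes, with 200 genes changed. The noise of each gene had its spread on the real arrays but was drawn independently of the other genes. Of the seeded genes, 40.3% were recovered at a log2 change of 0.5, 77.6% at 1 and 100% at 2, and 8 of 153 calls (5.23%) were false. On the real arrays 1114 genes were called, more than the 200 changed here. The adjusted threshold loosens as more genes change, so these shares need not hold for the real comparison. A simulated list of 40 genes shifted by 0.4 was called, and 0 of 22 lists without a shift were. These simulated lists had no correlation between members. They therefore do not show how often correlated lists are called without a shift. The real cell cycle list had an estimated correlation of 0.654.

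The alternatives were the mean of all probe sets of a gene, every probe set on its own, the dimmest 40% of genes left out, cyclic loess, median centring, a variance trend with robust fitting, array weights, the replicate number as a block and each array left out in turn. Centring on the 18 hybridisation control probe sets was added after the data were seen. Gene lengths, used in further checks, are the genomic spans in the RefSeq table. Random lists matched on signal were drawn 10000 times with a fixed seed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.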

Results

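Gene expression was measured on 6 oligonucleotide arrays in MCF-7, an established human breast cancer cell line of luminal type that carries the oestrogen receptor. In 3 of the arrays the RNA came from cells kept in normal medium, and in the other 3 from cells kept for 24 h in medium with 100 µM ATP, a nucleotide that acts outside cells on P2 receptors and is broken down there to adenosine. The arrays held 54675 probe sets, and 19775 genes were tested. The median linear signal lay between 30.7 and 31.9 on all 6 arrays. Across probe sets, which are not independent replicates, the log2 signals correlated with r = 0.996 for every pair of control arrays, with r = 0.993 to 0.996 between ATP arrays and with r = 0.990 to 0.994 between the groups. The first principal component held 45.7% of the variance and placed the 3 control arrays at -16.4 to -12.9 and the 3 ATP arrays at 9.29 to 21.5. The second held 24.6% and placed ATP replicates 1, 2 and 3 at -14.9, -9.90 and 16.9 and the control arrays at -6.17 to 10.1. ATP replicates 1 and 3 (r = 0.9932) were less alike than ATP replicate 1 and control replicate 2 (r = 0.9938). Levels below are log2 signals with the SD, changes are log2 differences of ATP minus control with the SE, and n = 3 arrays per group throughout. The labels call the replicates biological without saying what was kept separate, so the p-values measure the spread between these samples, and the number of arrays limits the precision.

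The comparison asked which transcripts differ between MCF-7 cells with and without ATP in the medium. Of 48 measured hypoxia and HIF target genes, which are switched on when oxygen is low, 27 rose with ATP and 0 fell. The largest rise of any called gene was that of *CGA*, the common alpha subunit of the glycoprotein hormones, at 7.91-fold. Camera called the cell cycle, histone and oestrogen response lists lower, though with adjusted p = 0.541, 0.156 and 0.555 with an estimated correlation. By the directional test of fry the histone list passed (adjusted p = 0.0119), and the cell cycle and oestrogen lists did not (0.0772 and 0.102). *CENPE*, the kinetochore motor protein, was 2.89-fold lower and *PGR*, the progesterone receptor, 1.96-fold lower. Genes of the nucleotide pathway itself were among those that rose, including *ENTPD1* and *NT5E*, the ectoenzymes that degrade ATP to AMP and AMP to adenosine, and *ADORA2B*, an adenosine receptor.

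At a Benjamini-Hochberg adjusted p under 0.05 in limma, 1114 of 19775 genes (5.63%) changed, 587 of them higher and 527 lower with ATP. At least 2-fold changes were found for 37 of the higher and 22 of the lower genes, and the median change was 0.50 among the rises and -0.53 among the falls. At an unadjusted p under 0.05 the count was 4135. The 3 ATP arrays all lay above or all below the 3 control arrays for 5332 genes, or 27.0% where chance gives 10%, and this held for each of the 1114 called genes. The split between rises and falls depended on the scaling, on single arrays and on the choice of probe sets. It was 437 higher and 665 lower without ATP replicate 1, and 230 and 99 without control replicate 2. With every probe set tested, 711 probe sets were higher and 1028 lower. With each array centred on its hybridisation controls, a choice made after these were seen to be brighter on the ATP arrays, the median change of all genes moved from 0.03 to -0.12, and 256 genes were higher and 1647 lower. The count fell to 289, 329 and 293 without control replicates 1, 2 and 3 and to 220 without ATP replicate 2, and the falls numbered 326 without ATP replicate 3.

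*CGA* rose from 6.03 ± 0.05 to 9.01 ± 0.20, a change of 2.98 ± 0.11 (adjusted p = 3.67e-05). *LOXL2*, a lysyl oxidase that cross-links collagen, rose by 2.05 ± 0.11 and *NDRG1*, a stress-responsive gene, by 2.03 ± 0.11, both with an adjusted p of 0.000341. *ADM*, which encodes the vasodilator peptide adrenomedullin, rose by 1.74 ± 0.18. The glycolytic genes *ALDOC* and *ENO2* rose by 1.60 ± 0.09 and 1.28 ± 0.15. *AQP3*, a channel for water and glycerol, rose by 1.55 ± 0.10 and *CEACAM5*, the carcinoembryonic antigen, by 1.39 ± 0.08. The other large rises were those of *RNF183* (1.58), *CEMIP* (1.36), which takes part in hyaluronan breakdown, *CSGALNACT1* (1.35), an enzyme of chondroitin sulphate synthesis, and *TMEM45A* (1.34). For *CGA*, *LOXL2*, *CEACAM5*, *CEMIP* and *CSGALNACT1*, only the brightest probe set passed the threshold, while the 3 probe sets of *AQP3* all did.

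**Figure D1:**
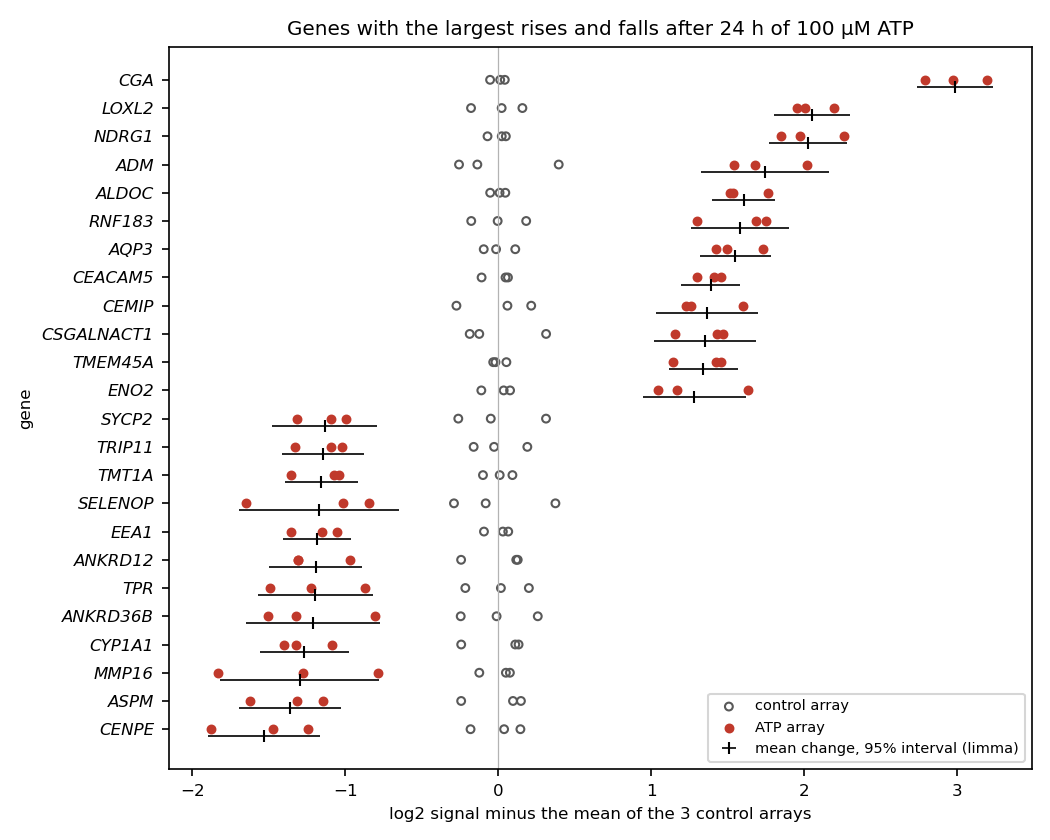
Log2 signal on each array minus the mean of the 3 control arrays (horizontal axis) for the genes with the largest rises and falls, with open points for control arrays, filled points for ATP arrays and a bar for the 95% interval of the mean change. The groups do not overlap for any of the 24 genes, because the genes were selected for this, and the mean changes run from 2.98 for CGA to -1.53 for CENPE.

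*CENPE* fell from 7.73 ± 0.17 to 6.20 ± 0.32, a change of -1.53 ± 0.16 (adjusted p = 0.0036), and *ASPM*, which acts at the poles of the mitotic spindle, changed by -1.36 ± 0.15 with all 3 of its probe sets past the threshold. *MMP16*, a membrane-bound matrix metalloproteinase, changed by -1.30 ± 0.23 and *CYP1A1*, a cytochrome P450 that oxidises aromatic hydrocarbons, by -1.27 ± 0.13. *TPR*, a filament protein of the nuclear pore, changed by -1.20 ± 0.16, *ANKRD12* by -1.19 ± 0.13 and *EEA1*, a tether of early endosomes, by -1.19 ± 0.10. *TRIP11*, which encodes a Golgi protein, changed by -1.15 ± 0.12, *SELENOP*, the selenium carrier, by -1.17 ± 0.23, *TMT1A*, a methyltransferase, by -1.16 ± 0.10 and *SYCP2*, a protein of meiotic chromosomes, by -1.14 ± 0.15. *MMP16*, *SELENOP*, *TMT1A* and *SYCP2* also had probe sets of the opposite sign that did not pass the threshold. *ANKRD36B* changed by -1.21 ± 0.19, but it has near-identical paralogs and its value is uncertain.

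Among the hypoxia and HIF target genes the median change was 0.45, and 34 members were higher and 1 lower when adjusted over the list alone. Besides *LOXL2*, *NDRG1*, *ADM*, *ALDOC* and *ENO2*, the rises included *BNIP3*, a mitophagy receptor, at 0.97 ± 0.08, *DDIT4*, an inhibitor of mTOR signalling, at 0.65 ± 0.10 and *VEGFA*, the vascular growth factor, at 0.56 ± 0.07. Camera gave the list an adjusted p of 1.22e-21, and an adjusted p = 0.14 with an estimated correlation. The count of 27 was 21, with 1 fall, under the hybridisation-control centring, 16 without control replicate 1 or 2 and 17 without control replicate 3 or ATP replicate 2. *EPAS1*, which encodes HIF-2α, rose by 1.11 ± 0.11 (adjusted p = 0.00294), with 1 of its 3 probe sets past the threshold. *HIF1A*, which encodes HIF-1α, differed by -0.31 ± 0.07 and did not pass (adjusted p = 0.0523).

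**Figure D2:**
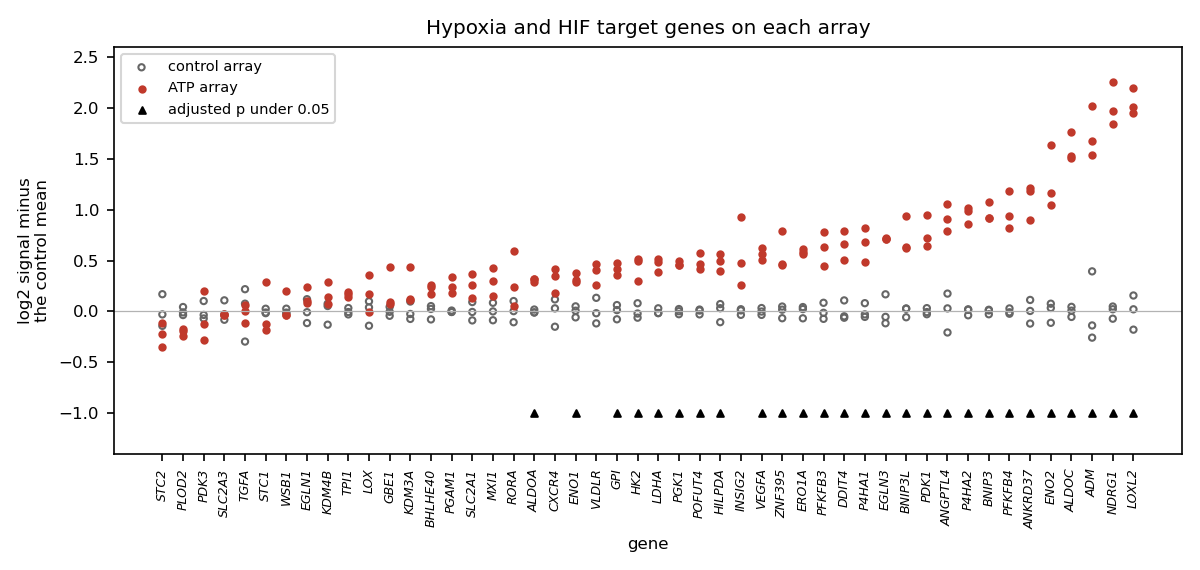
Log2 signal minus the mean of the control arrays (vertical axis) on each array for the 48 measured hypoxia and HIF target genes, ordered by mean change, with triangles under the 27 genes past the threshold. LOXL2 and NDRG1 rose by about 2.05 and 2.03, and STC2 and PLOD2 lie at the low end with mean changes of -0.23 and -0.20, neither past the threshold over all genes.

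Of 29 measured P2 and adenosine receptors and nucleotide-metabolising ectoenzymes, 4 rose and 0 fell, and 6 were higher when adjusted over the list alone. *ENTPD1* rose by 0.87 ± 0.12, *ADORA2B* by 0.62 ± 0.11, *NT5E* by 0.52 ± 0.10 and *ADA*, the deaminase that removes adenosine, by 0.51 ± 0.11. *ADA* lost its call with the replicate block and with the hybridisation-control centring. With every probe set tested, 1 of the 4 probe sets of *NT5E* passed. The P2 receptors named in advance did not pass: *P2RY2* differed by 0.23 ± 0.09 (adjusted p = 0.203) and *P2RX7*, at a low level of 3.02 ± 0.20 in control arrays, by 0.06 ± 0.13. The list had an adjusted p of 0.0177, and an adjusted p = 0.156 with an estimated correlation. Its median change of 0.09 was -0.05 with arrays centred on the hybridisation controls, 0.21 with dim genes left out, 0.06 without control replicate 2 and 0.17 without ATP replicate 1. Its 4 rises became 2 without control replicate 1 or 2 and 1 without control replicate 3 or ATP replicate 2. Among 30 measured purine and pyrimidine synthesis and salvage genes, 5 rose and 0 fell, with 8 higher when adjusted over the list alone. They included *UPP1*, which splits uridine, at 0.80 ± 0.11, and the adenylate kinases *AK1* at 0.62 ± 0.08 and *AK4* at 0.50 ± 0.07. The median of that list was 0.07, and -0.07 with the hybridisation-control centring, where 3 members were higher and 2 lower, and 0.11 without control replicate 2. The 5 rises became 2 without control replicate 3 or ATP replicate 2. Its adjusted p was 0.0146, which became 0.0617 without control replicate 3 and 0.053 without ATP replicate 1, and an adjusted p = 0.642 with an estimated correlation.

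In 33 immediate-early and MAPK feedback genes 7 rose and 0 fell (7 higher and 1 lower when adjusted over the list alone), with *EGR1*, a growth-factor-induced transcription factor, at 0.72 ± 0.09, *DUSP4*, a MAP kinase phosphatase, at 0.71 ± 0.08 and the ETS factor *ETV5* at 0.76 ± 0.13. *PHLDA1* rose by 0.70 ± 0.08 on its brightest probe set, while 1 of its 6 probe sets passed the threshold in the opposite direction at -0.56. The list's adjusted p was 0.00216, and an adjusted p = 0.14 with an estimated correlation. The median was 0.15, 0.00408 with the hybridisation-control centring and 0.09 without ATP replicate 3. With that centring 4 members were higher and 1 lower, and the 7 rises became 4 without control replicate 1 or 3 and 3 without control replicate 2 or ATP replicate 2. Of 37 NF-kB and inflammatory cytokine genes, 7 rose and 0 fell, and 14 were higher when adjusted over the list alone. The neutrophil chemokine *CXCL8* rose by 0.96 ± 0.16, the adhesion molecule *ICAM1* by 0.57 ± 0.08 and *TNF* by 0.52 ± 0.10 (list adjusted p = 1.75e-05, and adjusted p = 0.14 with an estimated correlation). The centring on hybridisation controls moved its median from 0.20 to 0.05 and left 2 of its members higher and 1 lower, and the 7 rises became 1 without control replicate 1, 2 without control replicate 2 or 3, 4 without ATP replicate 3 and 0 without ATP replicate 2. Of 46 interferon-stimulated genes, 8 rose and 1 fell, and 14 were higher and 1 lower when adjusted over the list alone. The exonuclease *ISG20* rose by 1.03 ± 0.09, the antiviral *OAS1* rose from 7.30 ± 0.23 to 8.30 ± 0.24 and the transcription factor *IRF7* rose by 0.62 ± 0.10. This list had an adjusted p of 1.75e-05, and an adjusted p = 0.555 with an estimated correlation. The median was 0.18, and 0.29 without ATP replicate 1. Under the hybridisation-control centring it was 0.04, and 5 members were higher and 2 lower. The 8 rises became 2 without control replicate 1 or ATP replicate 2, 5 and 3 without control replicates 2 and 3, and 14 without ATP replicate 1. Of 27 unfolded protein response genes, 3 rose and 0 fell, with 5 higher when adjusted over the list alone. They were the endoplasmic reticulum proteins *SDF2L1* (0.49 ± 0.10), *MANF* (0.45 ± 0.09) and *CALR* (0.37 ± 0.08), of which *CALR* had 0 of its 3 probe sets past the threshold when every probe set was tested. That list's adjusted p was 0.0102, 0.0642 without ATP replicate 1, and an adjusted p = 0.619 with an estimated correlation, and 0 of its members were called with the hybridisation-control centring, where its median of 0.15 became -2.87e-05. That median was 0.06 with the mean of probe sets. Its members called were also 0 without control replicate 1, 2 or 3 or ATP replicate 1 or 2.

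Both mesenchymal and epithelial lists held rises. Of 43 mesenchymal and invasion genes, 8 rose and 0 fell, and 9 were higher and 1 lower when adjusted over the list alone. *SOX9*, a transcription factor of progenitor cells, rose by 1.09 ± 0.13 with both of its probe sets past the threshold, *S100A4*, a calcium-binding protein linked to motility, by 0.88 ± 0.11, the matrix protein *TGFBI* by 0.85 ± 0.10 and fibronectin, *FN1*, by 0.64 ± 0.08. The classical markers *VIM* (-0.03 ± 0.12), *SNAI1* (0.18 ± 0.10) and *MMP9* (-0.04 ± 0.10) did not pass. The list's adjusted p of 0.0223 became 0.0532 without control replicate 2, 0.0793 without ATP replicate 3, 0.0563 with array weights and 0.064 with the replicate block, and the list had an adjusted p = 0.156 with an estimated correlation. Its median was 0.08, and -0.07 with the hybridisation-control centring, where 5 members were higher and 1 lower. The median was 0.16 with dim genes left out, 0.05 without control replicate 2 and 0.12 without ATP replicate 1. The 8 rises became 4 without control replicate 1 or 2 or ATP replicate 2, and 5 without control replicate 3. Of 38 epithelial junction and keratin genes, 6 rose and 1 fell, and 7 were higher and 1 lower when adjusted over the list alone. Keratin *KRT7* rose by 1.01 ± 0.14, the serine proteases *PRSS8* and *ST14* by 0.51 ± 0.07 and 0.44 ± 0.08, and the epithelial transcription factor *ELF3* by 0.48 ± 0.07. E-cadherin, *CDH1*, differed by 0.06 ± 0.07 with an interval of -0.11 to 0.23 and did not pass. This list had an adjusted p of 0.00923, and an adjusted p = 0.555 with an estimated correlation, and its median of 0.13 was -0.02 with the hybridisation-control centring, where 3 members were higher and 1 lower. Its 6 rises became 1 without control replicate 1 or 3, 3 without control replicate 2 and 0 without ATP replicate 2, and its 1 fall became 0 when any array but ATP replicate 1 was left out.

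Of 49 measured cell cycle and proliferation genes, 9 fell and 0 rose, and 15 were lower when adjusted over the list alone. Besides *CENPE*, the kinetochore protein *CENPF* fell by 1.11 on the log2 scale (SE 0.17), the checkpoint kinase *BUB1B* by 0.56 (SE 0.09) and cyclin *CCNE2* by 0.53 (SE 0.09). The proliferation marker *MKI67* differed by -0.56 ± 0.15 and *CDKN1A*, an inhibitor of cyclin-dependent kinases, by 0.25 ± 0.09, and neither passed. The median was -0.18, with an adjusted p of 1.52e-12, and an adjusted p = 0.541 with an estimated correlation. Under the hybridisation-control centring the median was -0.33. The 9 falls became 21 under that centring, 3 without control replicate 1 or 3 and 2 without control replicate 2 or ATP replicate 2. Of 29 histone genes, 8 fell and 0 rose, and 12 were lower when adjusted over the list alone. *H3C2* fell by 0.89 (SE 0.10), *H2BC4* by 0.72 (SE 0.09), *H2AC6* by 0.72 (SE 0.07) and *H2BC12* by 0.65 (SE 0.08). Histone genes have near-identical copies, so which copy a probe set reports is uncertain. The list's median was -0.19 with an adjusted p of 4.95e-09, and an adjusted p = 0.156 with an estimated correlation. The median was -0.33 with the hybridisation-control centring, -0.32 with dim genes left out and -0.28 without control replicate 1. Its 8 falls became 12 with the hybridisation-control centring, 4 without control replicate 2 or 3 and 5 without ATP replicate 2. Of 42 oestrogen response genes, 9 fell and 1 rose, and 12 were lower and 3 higher when adjusted over the list alone. *MYBL1* fell by 1.02 (SE 0.16), *PGR* by 0.97 (SE 0.12) and the fatty acid elongase *ELOVL2* by 0.88 (SE 0.09), while *CCN5*, a secreted matricellular protein, rose by 0.79 ± 0.09. With every probe set tested, 1 of 2 probe sets passed for *PGR* and for *ELOVL2*. For *MYBL1* 1 of 3 passed, and its probe sets reached a change of 0.09 in the opposite direction. The oestrogen receptor *ESR1* differed by -0.21 ± 0.07 and did not pass (adjusted p = 0.161). The list's median was -0.11 with an adjusted p of 0.000371, and an adjusted p = 0.555 with an estimated correlation. The median was -0.26 with the hybridisation-control centring, and -0.07 with the mean of probe sets, with array weights or without ATP replicate 3. Its 9 falls became 14 with the hybridisation-control centring, 2 without control replicate 1 or 2 or ATP replicate 2 and 3 without control replicate 3.

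**Figure D3:**
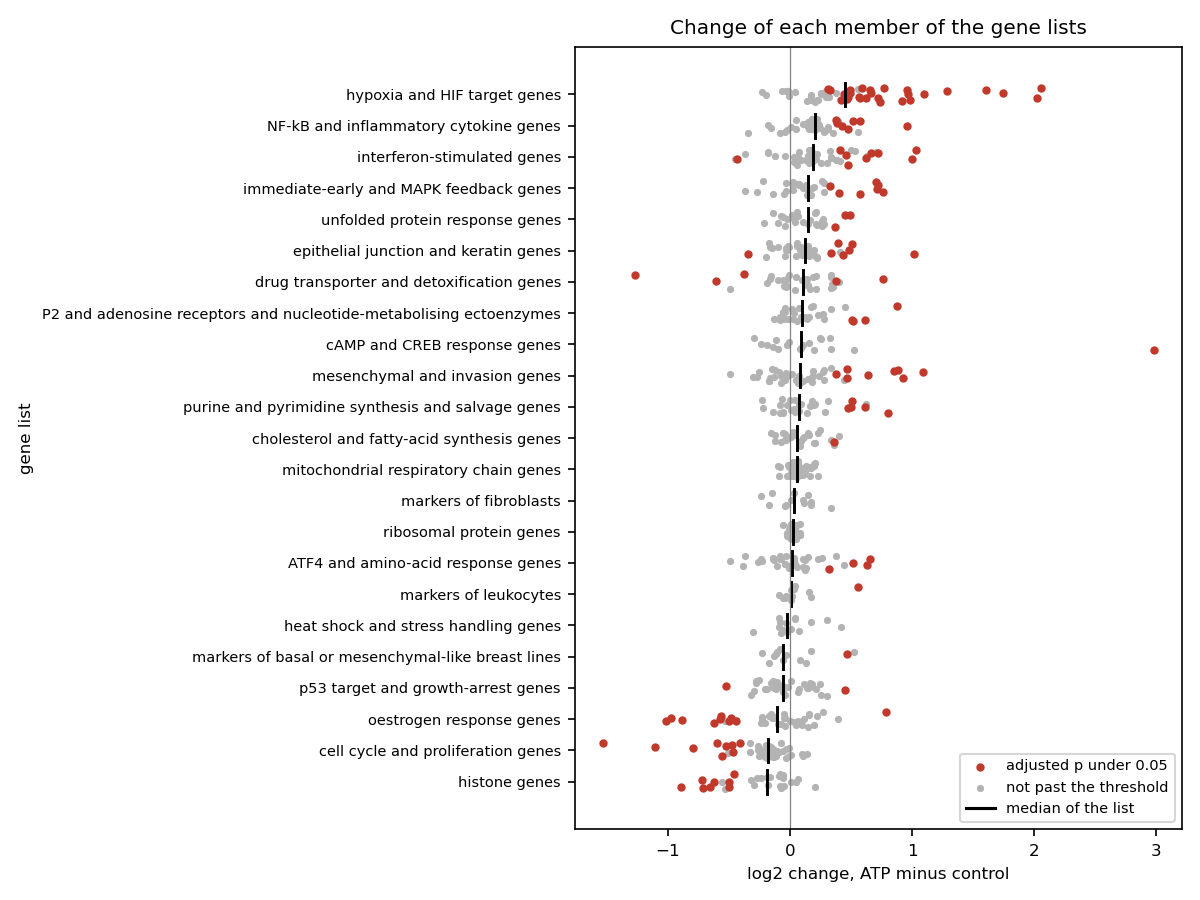
Log2 change, ATP minus control (horizontal axis), of each measured member of the 23 gene lists (vertical axis), with filled dark points for members past the threshold, grey points for the others and a vertical line at each list's median. The hypoxia list has the highest median, 0.45, and the histone and cell cycle lists the lowest, -0.19 and -0.18.

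The remaining 11 lists did not pass in camera. Of 19 cAMP and CREB response genes, *CGA* alone rose, and 2 were higher when adjusted over the list alone (list adjusted p = 0.182). That list did pass the directional test of fry (adjusted p = 0.00165), which does not compare it with other genes. Of the lists called by camera, the purine (0.0512), unfolded protein (0.0713), cell cycle (0.0772), interferon (0.0987) and oestrogen (0.102) lists did not pass fry. Among 35 p53 target and growth-arrest genes, *GDF15*, a stress-induced cytokine, rose by 0.45 ± 0.10 and the kinase inhibitor *CDKN2B* fell by 0.53 (SE 0.12), the same counts as when adjusted over the list alone (list adjusted p = 0.182). Of 37 genes on the list named ATF4 and amino-acid response, 4 rose, with 5 higher and 3 lower when adjusted over the list alone (list adjusted p = 0.89). Among the 4 were *TXNIP* at 0.52 ± 0.11 and *ARRDC4* at 0.63 ± 0.09. Their place on the list was fixed in advance, and whether ATF4 acts on them was not tested. *DDIT4*, also among the 4, stands on the hypoxia list as well. Of 34 drug transporter and detoxification genes 2 rose and 3 fell, with 6 higher and 4 lower when adjusted over the list alone (list adjusted p = 0.469). They included *GSTA4*, a glutathione transferase, at 0.76 ± 0.11 and *CYP1B1*, a cytochrome P450, at -0.61 ± 0.10, whereas the transporters *ABCB1* (-0.02 ± 0.08) and *ABCC1* (0.21 ± 0.07) did not pass. Of 28 cholesterol and fatty-acid synthesis genes *FASN* alone was called higher, by 0.36 ± 0.08, and 0 were called when adjusted over the list alone (list adjusted p = 0.153). On its brightest probe set *SCD*, of the same list, was not called (0.40 ± 0.11). When every probe set was tested, 3 of the 4 probe sets of *SCD* passed, all upward, and the largest change among the 4 was 1.03. No member of the 38 ribosomal protein genes (list adjusted p = 0.857), 40 mitochondrial respiratory chain genes (0.0854), 15 heat shock and stress handling genes (0.857) or 13 fibroblast markers (0.857) was called, over all genes or over the list alone. At an unadjusted p under 0.05 in limma the counts were 0 ribosomal, 3 respiratory chain, 3 heat shock and 2 fibroblast genes. With a variance trend and robust fit, limma called 7 respiratory chain genes and 1 ribosomal gene higher, and 1 heat shock gene higher and 1 lower. The heat shock list had a median of -0.03 and a mean of 0.02, and camera placed it downward. Of 12 leukocyte markers *CD8A* rose by 0.55 ± 0.11 at a low level of 4.46 ± 0.18 in control arrays (list adjusted p = 0.857). Of 13 markers of basal or mesenchymal-like breast lines *CD44*, a hyaluronan receptor, rose by 0.47 ± 0.09 (list adjusted p = 0.871), and this list had a median of -0.06, a mean of 0.03 and a downward direction in camera, with 2 members higher when adjusted over the list alone. Single arrays and processing choices decided several of these calls. *FASN* was not called without any 1 control replicate or without ATP replicate 1 or 2, *CD44* without any 1 control replicate or ATP replicate 2, and *CD8A* without control replicate 1 or 3 or ATP replicate 2 or 3. Neither *CD44* nor *CD8A* was called with the hybridisation-control centring. Of the 13 probe sets of *CD44*, however, 7 passed upward when each was tested, and the 13 ranged from -0.06 to 1.25. *FASN* also lost its call with the mean of its probe sets, with median centring, with the replicate block or with the hybridisation-control centring. With every probe set tested, 0 of its 2 probe sets passed, and the other one had a change of -0.10. *GDF15* kept its call without control replicate 1 and lost it without any other array, and *CDKN2B* kept its call without ATP replicate 3 and lost it likewise. *GDF15* also lost it with median centring and *CDKN2B* with the mean of its probe sets and the replicate block. When every probe set was tested, 0 of the 3 of *GDF15* and 0 of the 2 of *CDKN2B* passed, where the other probe set of *CDKN2B* had a change of 0.18. The 2 rises of the drug transporter list became 1 when any array but ATP replicate 3 was left out, and its 3 falls became 1 without control replicate 2 or 3 or ATP replicate 2. The 4 rises of the ATF4 list became 1 without control replicate 1 or 2 or ATP replicate 2, and 2 without control replicate 3 or ATP replicate 1. With the hybridisation-control centring 0 p53 target genes were higher and 6 lower, 2 ATF4 genes were higher and 5 lower, and 1 drug transporter or detoxification gene was higher and 5 lower.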

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

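The tests of the control probe sets were chosen after the data were seen. The 18 hybridisation control probe sets, which report bacterial and phage transcripts added in fixed amounts and lie outside the gene comparison, were brighter on the ATP arrays. Their mean log2 signal was 10.48 ± 0.05 (SD, n = 3) on the control arrays and 10.63 ± 0.04 on the ATP arrays, a difference of 0.146 with all 3 ATP arrays above all 3 control arrays (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allow). The mean hid an uneven difference: the 6 bioB probe sets differed by 0.230 without overlap, and the 4 cre probe sets by 0.0398 with overlapping groups (exact permutation p = 0.3). The cre signals, at 13.28 ± 0.02 on the control arrays, lay close to the highest signal on any array, 13.98, and whether the shift was uniform stays open. The 24 poly-A control probe sets, for transcripts added before labelling, differed by 0.140, from 6.65 ± 0.11 to 6.79 ± 0.16 with overlapping groups (exact permutation p = 0.3).

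Probe sets that name no single gene also changed. Of 11721 probe sets with no listed gene, 237 passed the threshold of limma when every probe set was tested, 48 of them higher and 189 lower. Of 1801 probe sets with several gene symbols, 64 passed, 27 higher and 37 lower. Among 41091 probe sets with 1 symbol, 636 were higher and 802 lower.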

How the results depend on the processing

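Choices were changed 1 at a time, except that the variance trend and robust fitting were changed together, and the centring on hybridisation controls was the only setting added after the data were seen. No called named gene changed sign on its brightest probe set or on the mean of its probe sets, and camera placed no called list in the opposite direction, which it takes relative to the other genes. The medians of the P2 and adenosine, purine, mesenchymal, epithelial and unfolded protein lists did turn negative with the hybridisation-control centring (-0.05, -0.07, -0.07, -0.02 and -2.87e-05), and 1 probe set of *PHLDA1* passed in the opposite direction (-0.56). The 1114 called genes (587 higher, 527 lower) became 1989 (1040, 949) with the dimmest 40% of genes left out, 1848 (964, 884) with cyclic loess, 2272 (1139, 1133) with a variance trend and robust fit, 1991 (1171, 820) with array weights and 1903 (256, 1647) with hybridisation-control centring. With every probe set tested, 1739 probe sets rather than genes passed (711, 1028). With the mean of all probe sets (845) and median centring (981) the counts stayed within 1.5 times. Leaving out 1 array gave 220 to 1102 genes, 134 to 639 higher and 86 to 665 lower, with fewer arrays as a known reason: 289 (164, 125), 329 (230, 99) and 293 (164, 129) without control replicates 1, 2 and 3, and 1102 (437, 665), 220 (134, 86) and 965 (639, 326) without ATP replicates 1, 2 and 3. Of the 81 called named genes, 45 to 76 were kept without 1 array, 66 with hybridisation-control centring, 68 with the mean of probe sets, 78 with median centring, 76 with every probe set and all 81 with cyclic loess, trend and robust or array weights. The replicate number as a block gave 1229 genes (633, 596) and kept 77 of those 81. The genes lost were *ADA*, *FASN*, *WARS1* and *CDKN2B* with the block, *GDF15*, *FASN* and *WARS1* with median centring, and *GDF15*, *CALR*, *FASN*, *WARS1* and *CDKN2B* with every probe set. With the mean of probe sets they were *ICAM1*, *NT5E*, *AK4*, *ST14*, *TNIP1*, *AKR1C1*, *FASN*, *WARS1*, *CCNE2*, *CDKN2B*, *MYBL1*, *TMT1A* and *SELENOP*. With the hybridisation-control centring they were *CD8A*, *TNF*, *TXNIP*, *ADA*, *SDF2L1*, *ADSS1*, *CD44*, *MANF*, *GDF15*, *ST14*, *TNIP1*, *AKR1C1*, *CALR*, *FASN* and *WARS1*. Without ATP replicate 2 the 36 lost were *KRT7*, *OAS1*, *CXCL8*, *ETV5*, *IFI35*, *DDIT4*, *IRF7*, *ADORA2B*, *ICAM1*, *CD8A*, *NT5E*, *TNF*, *TXNIP*, *ADA*, *PRSS8*, *AK4*, *SDF2L1*, *ELF3*, *ADSS1*, *CD44*, *MANF*, *GDF15*, *ST14*, *TNIP1*, *AKR1C1*, *CALR*, *FASN*, *WARS1*, *CCNE2*, *CDKN2B*, *BUB1B*, *CYP1B1*, *MYBL1*, *SELENOP*, *ANKRD36B* and *MMP16*, and the genes lost without any other array were all among them. Deviations of same-numbered arrays from their group means correlated at 0.07, 0.30 and 0.34 over genes. Only ATP replicate 1 deviated most like another number, control replicate 2, so pairing stays open.

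With an estimated correlation the adjusted p of the 12 called lists was 0.140 (hypoxia, immediate-early, NF-kB), 0.156 (P2 and adenosine, mesenchymal, histone), 0.541 (cell cycle), 0.555 (epithelial, oestrogen, interferon), 0.619 (unfolded protein) and 0.642 (purine). Without 1 array their preset adjusted p ran from 2.3e-22 to 3.89e-17 (hypoxia), 0.00177 to 0.00541 (immediate-early), 2.86e-06 to 0.000612 (NF-kB), 0.0139 to 0.0295 (P2 and adenosine), 0.0139 to 0.0793 (mesenchymal), 2.41e-10 to 4.15e-07 (histone), 1.81e-14 to 5.01e-08 (cell cycle), 0.00383 to 0.0343 (epithelial), 9.26e-05 to 0.00424 (oestrogen), 4.96e-09 to 0.0029 (interferon), 0.00249 to 0.0642 (unfolded protein) and 0.00383 to 0.0617 (purine). The mesenchymal list had 0.0563 with array weights and 0.064 with the replicate block. The respiratory chain list passed with the mean of probe sets (0.0439), cyclic loess (0.0244), trend and robust (0.00349), array weights (0.0159) and without control replicate 2 (0.0468) or ATP replicate 3 (0.00535), over a range of 0.00535 to 0.348 without 1 array. The cholesterol list passed with the mean of probe sets (0.0311), array weights (0.0429) and without ATP replicate 3 (0.0303), over 0.0303 to 0.648. The block changed no other list call, and the cause of these changes was not tested. Signal over background limits what the dim genes can show.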

Other observations

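The tests of gene families, of gene length, of RNA integrity and of aryl hydrocarbon receptor genes in this part were chosen after the data were seen. Gene families with at least 10 measured members, taken from the stem of the symbol, were tested for called genes by Fisher's exact test, 460 tests over 230 families. The S100 genes were the exception. Their stem would be S alone, so they were grouped by a separate rule on their names, and their test is not part of a uniform scan. The test takes the members as independent and sets them against all other genes, unmatched on signal or length. Members that change together, or probe sets that read near-identical copies, can make its p-values too small. The S100 family of small calcium-binding proteins had 8 of 20 measured members higher and 0 lower (Fisher's exact test, adjusted p = 1.22e-05). *S100P* rose by 1.06 ± 0.07 (log2 change and SE, n = 3 arrays per group), *S100A14* by 0.97 ± 0.08, *S100A6* by 0.93 ± 0.09 and *S100A7* by 0.92 ± 0.14, beside *S100A4* (0.88), *S100A16* (0.61), *S100A10* (0.53) and *S100A13* (0.44). In each all 3 ATP arrays lay above all 3 control arrays, which held for every gene called higher and adds no support. All 8 stayed higher with cyclic loess and with median centring, and 7 with arrays centred on the hybridisation controls.

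Among the kinesins, motor proteins of microtubules, 8 of 38 were lower and 2 higher (Fisher's exact test for the lower, adjusted p = 0.000894). The mitotic kinesins *KIF20B*, *KIF14*, *KIF18A* and *KIF23* changed by -0.97 ± 0.10, -0.77 ± 0.16, -0.61 ± 0.13 and -0.60 ± 0.14, and the transport motor *KIF5B* by -0.52 ± 0.10, whereas *KIF3C* rose by 0.56 ± 0.09. Of 36 genes with the RNA-binding motif stem RBM, 6 were lower and 0 higher (Fisher's exact test, adjusted p = 0.0395), among them *RBM25* at -0.64 ± 0.10 and *RBM14* at -0.64 ± 0.08. Of 14 genes of the H2BC histone cluster, 7 were lower and 0 higher (Fisher's exact test, adjusted p = 1.22e-05). *H2BC11* changed by -1.05 ± 0.08, from a low level of 5.02 ± 0.03 (SD) in control arrays. Near-identical copies make both the single genes and the p-value of this family uncertain. *H2BC3*, *H2BC4*, *H2BC6*, *H2BC9* and *H2BC12* also stand on the histone list, and *KIF11* and *KIF23* on the cell cycle list. Their calls are the same in both places and are not separate evidence. The called members of these families kept their calls with cyclic loess and median centring, and with the hybridisation-control centring except for 1 kinesin, and the family members called lower then numbered 12, 10 and 8.

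Genes lower with ATP were long. Their median length was 62.2 kb, against 21.4 kb for the higher genes and 24.1 kb for the genes not called, with a length known for at least 99.8% of each set, and random genes matched on signal had medians of 25.7 to 33.7 kb (central 95%). With all genes ordered by length in 4 equal bins, the calls from the shortest to the longest bin were 37, 65, 178 and 246 lower and 166, 149, 153 and 118 higher. Removing a loess curve on length from each array narrowed the gap, to medians of 51.0 kb for the genes then lower and 31.6 kb for those then higher. A trend shared by genes of every signal may therefore make part of the pattern, but is argued against as the whole cause. The 51.0 kb lay above all 1000 signal-matched random sets (highest 35.6 kb). The curve was fitted over genes of all signals, while the lower genes were brighter than those not called (median log2 signal 8.11 against 5.88). It moved the median change of the lower genes only from -0.526 to -0.524. The test therefore cannot exclude a trend with length confined to bright genes. RNA integrity stays open: the 3' minus 5' signal of actin, GAPDH and STAT1 control probe sets differed by 0.0341 on average (SE 0.0547), too small against its error to argue for or against it. An effect of ATP itself on long genes may also apply and was not tested separately.

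In the hypoxia list 27 of 48 members were higher, and the adjusted p of 1.22e-21 was 0.14 with an estimated correlation. The rise was set against 2 technical explanations. The list's median of 0.45 lay at percentile 100 of 10000 random lists matched on signal, whose highest median was 0.14, which argues against the signal level of its genes. An array-wide scale difference of the mean size seen in the hybridisation controls is also argued against, since 21 of the 27 called members stayed higher and past the threshold with arrays centred on those controls. One hypothesis is therefore that the rise is a response to ATP, found and examined on the same arrays. Whether cell density or oxygen in the culture differed between the groups was not measured here and stays open.

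In the cell cycle list 9 of 49 members were lower, and its adjusted p was 0.541 with an estimated correlation, itself estimated at 0.654. Its lower median was set against the length and signal of its genes. The median of -0.18 lay at percentile 0 of 10000 random lists matched on both, whose lowest median was -0.10. Among members the 26 shorter than the median of all genes had a median change of -0.17 with 2 called, and the 23 longer ones -0.20 with 7 called. A response to ATP may explain the falls, though the members move together and the list did not pass once that was estimated, and RNA integrity, open as above at 0.0341, was not excluded for the long members.

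*CYP1A1* and *CYP1B1*, both targets of the aryl hydrocarbon receptor, changed by -1.27 ± 0.13 and -0.61 ± 0.10. A lower activity of that receptor may be a candidate explanation. Of 6 other genes of its battery (*CYP1A2*, *AHRR*, *TIPARP*, *NQO1*, *ALDH3A1*, *UGT1A6*), 0 were lower and past the threshold in limma, and 0 were higher, with 0 of them also at an unadjusted p under 0.05. The interval of each excluded a fall of 0.5, but only 2 of them, *TIPARP* at -0.16 and *NQO1* at 0.13, had a signal above the median of all genes, so the test leaves this hypothesis open.

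The 6 arrays can be split into 3 and 3 in 10 ways, which is too few for a share under 0.05. The real split was the 1 with as large a result in each case. It gave 1114 called genes, 587 higher and 527 lower, against at most 0 in the other splits, and 12 gene lists against at most 6. Every other split puts control and ATP arrays on both sides, so a difference between the groups enters the spread. Low gene counts there were thus built in, and the contrast with 0 is no evidence against chance. With the preset correlation, camera called from 2 to 6 lists in each of those mixed splits.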
